A study of Homo sapiens with 6 samples.

How the data were processed

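Total RNA of HCT116 cells was amplified with random primers along whole transcripts and labelled with 1 dye, per the labels' protocols, and each of 6 samples was hybridised to an array of its own. The groups, 3 control siRNA and 3 ALYREF siRNA samples treated with 20 nM siRNA for 48 h, were taken from the sample titles. The authors' scanner files hold the spot intensity after background subtraction and spatial detrending by Agilent Feature Extraction 11.0.1.1, per the file headers, with no scaling between arrays. The authors also deposited a table of log2 values whose normalization is not given in the sources used here. Set against the scanner files, its columns correlated at 0.9977 to 0.9998 with the log2 signals of the same arrays, and differed from a quantile normalization of them by a median of 0.0007 to 0.0011. The median of each of its 6 columns was 6.20, and the table was used only as an alternative. Its scale, centring and direction were settled by that comparison, while the tool that made it stays unknown.

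Each array held 62921 spots, 61482 of them not marked as controls. Control spots were left out of the tests, and so were the probes whose names start with ASSPINKEIN, CUST or Negative. Spots marked as outliers by the scanner software, 81 to 377 per array, were left out. No spot was saturated. The log2 processed signal was expressed relative to the 75th percentile of each array, and spots of the same probe were averaged. A probe was kept when it was well above background on at least 3 of the 6 arrays, judged for probes with several spots by at least 0.5 of their spots; 45970 of 60546 probes were kept, and 45808 of these had values on at least 2 arrays of each group. Median local background was 20 to 21 intensity units. The SD between the spots of a named probe within an array had a median of 0.03 log2 units over the 45 genes tested.

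Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05 on the adjusted p. A 2-fold threshold is an absolute log2 fold change of at least 1. Every adjusted p of a gene or probe in the text comes from this fit. Groups of probes were tested with camera (preset correlation 0.01), and with camera with an estimated correlation and fry as alternatives, adjusted over the 3 panel groups with at least 5 tested members. The design text speaks of independent experiments, so p-values measure the spread between them, as far as each array is a separate experiment. An exact test of 3 against 3 arrays has 0.1 as its smallest two-sided permutation p, so none is given for single genes.

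Gene names came only from RefSeq accessions in the scanner files, matched without versions to a RefSeq table of assembly GRCh38.p14. Of the 50 probes with Agilent catalogue names, 49 matched and 1 did not. The grid of the arrays is annotated to hg19, so no coordinates are given. The other identifiers are catalogue numbers that the files and tables used here do not pair with genes. The planned tests of ALYREF itself, of protein-coding and long non-coding genes as classes, of 31 gene lists and of single-exon genes therefore could not be made as designed. In their place the kinds of identifier were compared as such, and the 49 named genes were sorted into groups from their names alone, before their values were examined.

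Before the data were examined, the rule for named genes was fixed as follows. It takes ALYREF, the 8 largest rises and 8 largest falls of protein-coding genes and up to 5 of each of long non-coding RNAs with a symbol, with an adjusted p under 0.05, groups that do not overlap and signal well above background on all 3 arrays of a group, and per list up to 4 members that passed or 2 that did not. It also takes several fixed genes, none of which was among the named probes, and GAPDH where scaling is discussed. Identifiers without a name were limited to the 2 largest rises and 2 largest falls among probes well above background on all 6 arrays. The alternatives fixed at the same time were normexp background correction (offset 50), quantile normalization, other scalings, the authors' values, other filters, a replicate block, a trended and robust variance model and leaving out each array. Normexp was run on the median spot signal, since the files hold no mean signal. Cyclic loess and the slide row and slide column of an array as blocks were chosen after seeing the data.

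The fit was tested on simulated data with the real probes' means and variances, in which 67, 67 and 66 probes were changed by 0.5, 1 and 2 log2 units, for the comparison of ALYREF siRNA with control siRNA over 45347 probes. It recovered 95.5% of the changes of 2 log2 units, 50.7% of those of 1 unit and 0% of those of 0.5 units, with 3 false calls among 45147 unchanged probes. With so few probes changed the adjusted threshold is stricter than in the real comparison. Noise was drawn independently for each probe and array, so shifts shared by many probes, as between the real arrays, were absent. The 3 false calls therefore do not measure errors that such shifts bring. Figures were drawn from the tabulated values.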

Results

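Total RNA was measured in HCT116 cells, an established human colorectal cancer cell line, 48 h after transfection with 20 nM of a negative control siRNA or of an siRNA against ALYREF. ALYREF is an RNA-binding adaptor of the mRNA export machinery. Each group held 3 arrays, and each array carried the RNA of a single culture on a 1-colour oligonucleotide array. The series design describes 3 independent experiments. The 6 arrays lay on 1 slide and were read in 1 scan, with the 3 control arrays and ALYREF replicate 1 in the upper row of array positions and ALYREF replicates 2 and 3 in the lower row. The median processed signal of an array lay between 66.5 and 86.4 intensity units, and 67.3% to 76.6% of the spots were well above background. Arrays of the same group correlated at r = 0.993 to 0.997 across the tested probes, and arrays of different groups at r = 0.983 to 0.993; probes are not independent replicates. No pair of arrays held identical values. The number of arrays limits the precision of every value below.

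The comparison asked what silencing ALYREF does to gene expression in these cells. Of 60546 probes, 49 could be paired with a gene symbol, and none of these 49 reads ALYREF, so the knockdown itself was not checked here. The genes that could be named form a panel of protein-coding genes read by 10 spots per array. Of these, 45 were tested, 8 rose with ALYREF siRNA and 4 fell (limma, adjusted p under 0.05), and 33 did not pass. CCNA2 (cyclin A2, which drives S phase and the entry into mitosis) had the largest rise, 2.004-fold, and COL13A1 (a transmembrane collagen) the largest fall, 1.91-fold. All values are log2 signals relative to the 75th percentile of the array unless a fold is stated. How many of the called genes were higher depended on this scale and on single arrays: 66.7% here, 30.8% of 13 called genes when arrays were centred on their median, and 92.9% of 14 when the 75th percentile was taken over probes well above background on all 6 arrays. Without ALYREF replicate 2 it was 36.4% of 11 called genes, and without ALYREF replicate 1 it was 83.3% of 12.

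Genes of mitosis and the centromere made up most of the rises. In this group, formed from the gene names before their values were examined, 5 of 7 genes rose and none fell. CCNA2 stood at 1.994 ± 0.196 with control siRNA and at 2.996 ± 0.266 with ALYREF siRNA (SD, n = 3; log2 fold change 1.003, SE 0.17, limma adjusted p = 0.00726). SPDL1, which brings dynein to the kinetochore, went from 1.80 ± 0.13 to 2.58 ± 0.30, a 1.72-fold rise (SD, n = 3; limma adjusted p = 0.0140). The mitotic kinesin KIF20A rose 1.40-fold, the centromere protein ITGB3BP 1.36-fold and the kinetochore motor CENPE 1.33-fold, with limma adjusted p of 0.0270, 0.0477 and 0.0328. In each of these 5 genes the 3 ALYREF arrays lay above the 3 control arrays. CENPQ, an inner kinetochore protein, had a log2 fold change of 0.46 (SE 0.14) with a limma adjusted p of 0.0514, and PIMREG, a regulator of mitosis, one of -0.01 (SE 0.10) with a limma adjusted p of 0.945. These last 2 genes are named because they complete the group, a choice made after their values were seen. As a group the 7 genes had a median log2 fold change of 0.46 and shifted upward against all other probes (camera, preset correlation, adjusted p = 0.00400). That call was lost with an estimated correlation (adjusted p = 0.658), while fry, which asks only whether the genes move one way on balance, gave an adjusted p of 0.0389. With the slide row as a block, or within the upper row, the median was 0.30. That is the value of the single array ALYREF replicate 1 against the 3 controls, and no other ALYREF array enters it. With the slide column as a block the median was 0.58 (camera adjusted p = 0.0207), in a fit that rests on columns 1 and 2 alone with 1 residual degree of freedom. KIF20A kept its call in 10 of 19 alternative fits and ITGB3BP and CENPE in 8 each, with losses under median centring and without a filter on dim probes in all 3 genes, and each value stayed above 0. ALYREF replicate 2 read higher than the others in this group: the median of the 7 genes against their control mean was 0.68 on that array, 0.30 on replicate 1 and 0.40 on replicate 3.

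**Figure D1:**
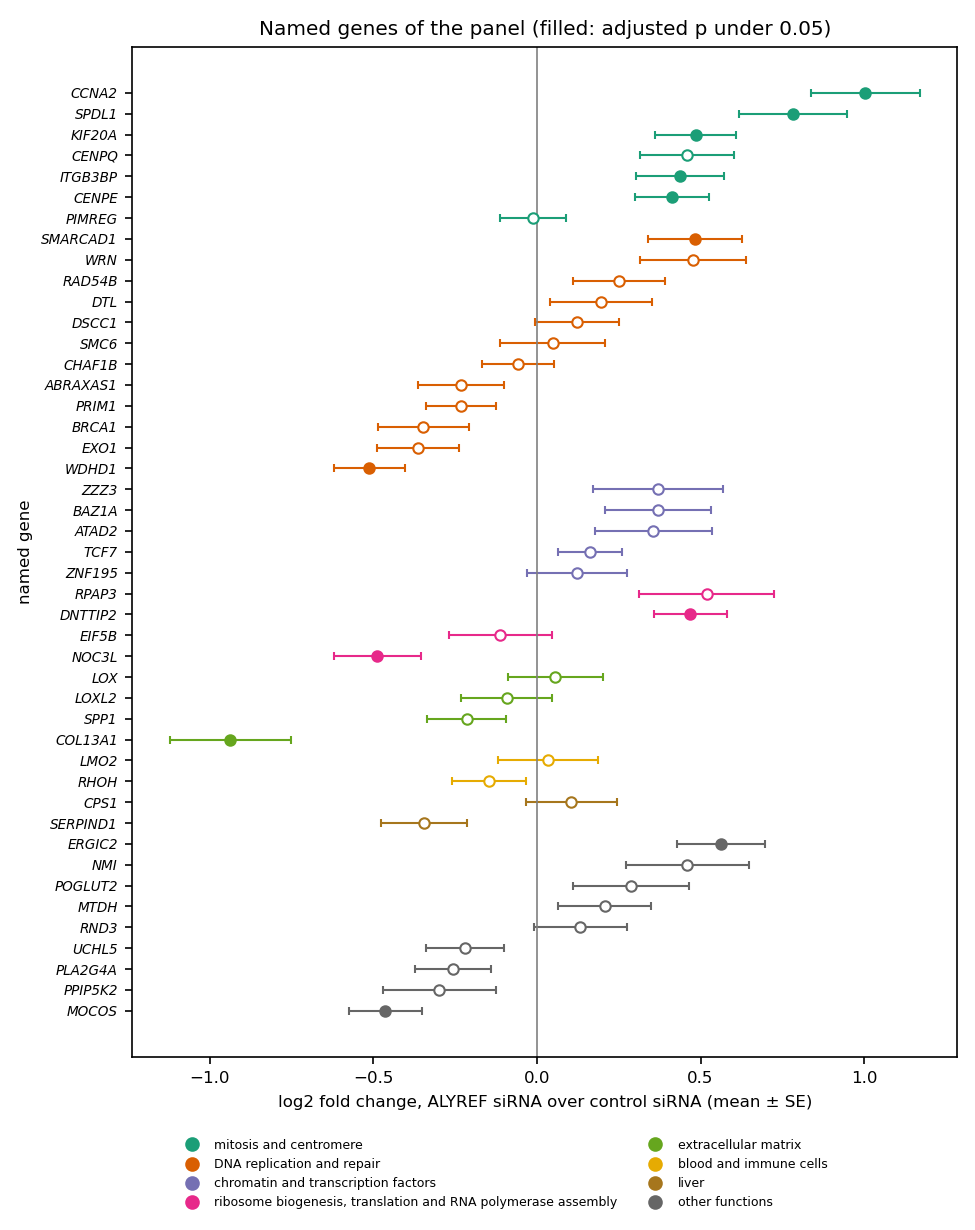
Log2 fold change (x axis) of the 45 tested genes of the named panel (y axis), ALYREF siRNA over control siRNA. Points are means of 3 against 3 arrays, bars are 1 SE from limma, colours give the group a gene belongs to and filled points have an adjusted p under 0.05. CCNA2 at 1.003 and COL13A1 at -0.94 lie farthest from 0.

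Genes of DNA replication and repair did not move one way on the scale used here. Among the 12 tested, 1 rose, 1 fell and 10 did not pass, and the median log2 fold change was -0.01, with -0.12 under median centring, 0.14 under the other 75th percentile, 0.25 under quantile normalization and cyclic loess and 0.26 with the authors' values. SMARCAD1, a chromatin remodeller that acts in the processing of broken DNA ends, rose 1.40-fold (0.83 ± 0.13 against 1.32 ± 0.22, SD, n = 3; limma adjusted p = 0.0434). WDHD1, a component of the replication fork, fell 1.43-fold (1.79 ± 0.07 against 1.27 ± 0.10, SD, n = 3; limma adjusted p = 0.0141). Each of these scalings gave calls of one direction in this group: under median centring WDHD1, EXO1, PRIM1 and BRCA1 were called lower and no gene higher, and under the other 75th percentile SMARCAD1 and WRN were called higher and no gene lower. WDHD1 also lost its call with quantile normalization, cyclic loess and the authors' values. The helicase WRN had a log2 fold change of 0.48 (SE 0.16) and the exonuclease EXO1 one of -0.36 (SE 0.13), with limma adjusted p of 0.0664 and 0.0694. The primase subunit PRIM1 had -0.23 (SE 0.11) and the chromatin assembly subunit CHAF1B -0.06 (SE 0.11), with limma adjusted p of 0.153 and 0.737. The group did not differ from all other probes (camera adjusted p = 0.742; 0.922 with an estimated correlation), and its median was -0.16 on ALYREF replicate 1 alone, which is all that remains with the slide row as a block. When fry was asked whether its genes change in either direction, the adjusted p was 2.79e-06. That test does not compare the group with other probes. Since 24.4% of all tested probes were called, it does not show a change particular to these genes. The other panel genes, outside the mitosis group, also read higher on ALYREF replicate 2, where their median against the control mean was 0.27, compared with -0.08 and -0.02 on replicates 1 and 3.

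Changes in the remaining named genes were scattered over several functions. COL13A1 fell from 0.60 ± 0.07 to -0.34 ± 0.38 (SD, n = 3; log2 fold change -0.94, SE 0.19, limma adjusted p = 0.0116), and the other 3 extracellular matrix genes did not pass. Of the 4 genes of ribosome biogenesis, translation and RNA polymerase assembly, the nucleolar protein DNTTIP2 rose 1.38-fold and the ribosome biogenesis factor NOC3L fell 1.40-fold, with limma adjusted p of 0.0210 and 0.0328. NOC3L kept its call in 5 of 19 alternative fits. ERGIC2, a protein of transport between the endoplasmic reticulum and the Golgi, rose 1.48-fold and MOCOS, the molybdenum cofactor sulfurase, fell 1.38-fold, with limma adjusted p of 0.0210 and 0.0208; they kept their calls in 13 and 10 of 19 alternative fits. The 5 chromatin and transcription factor genes all had log2 fold changes above 0, with a median of 0.36, but none passed and the group did not either (camera adjusted p = 0.138; 0.685 with an estimated correlation). The group passed with quantile normalization, at a median of 0.62 (camera adjusted p = 0.0171), and its median was 0.11 with the slide row as a block, on ALYREF replicate 1 alone, and 0.15 without ALYREF replicate 2.

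Of the 31 gene lists fixed beforehand, 5 had any member among the named genes, and none had the 5 members needed for a test of the list. In the list of G2/M and mitosis genes all 3 measured members, CCNA2, KIF20A and CENPE, rose, over all probes tested and adjusted over the list alone. In the DNA repair list 0 of 4 passed over all probes tested; adjusted over the list alone, WRN was higher and EXO1 and BRCA1 lower. BRCA1, named after its values were seen, had a log2 fold change of -0.35 (SE 0.14, limma adjusted p = 0.106). Neither PRIM1 nor CHAF1B of the list of G1/S and DNA replication genes passed either way. LOX, of the glycolysis and hypoxia list, had a log2 fold change of 0.06 (SE 0.14), and TCF7, of the WNT list, one of 0.16 (SE 0.10); their limma adjusted p were 0.807 and 0.270, and neither passed when adjusted over the list alone.

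The calls on single named genes depended on the arrays used. Of the 12 genes called, CCNA2, SPDL1 and COL13A1 kept their call whichever array was left out; 3 genes were called without ALYREF replicate 3, and 4 without control replicate 1 or without control replicate 2. With the slide row as a block, where ALYREF replicate 1 alone is set against the controls, 0 of the 12 were called by limma (10 named genes had an unadjusted p under 0.05), and the log2 fold changes were 0.78 for CCNA2, 0.52 for SPDL1 and -1.17 for COL13A1. These fits have 1 array in the ALYREF arm, which is assumed to vary like the other arrays.

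Over all probes, 11188 of the 45808 tested changed (24.4%), 5262 higher and 5926 lower with ALYREF siRNA (limma, adjusted p under 0.05). The groups did not overlap in 45.2% of the tested probes, where chance gives 10% on average. Shifts shared by many probes of an array, whether from the siRNA or from slide position, can move the share far from that. Among 46 control and CUST probes left out of the tests, 2 lay fully higher and 15 fully lower on the ALYREF arrays. At least 2-fold changes were called in 2290 probes, 1326 higher and 964 lower, and 231 of these were not well above background on any array of one group, so that their fold is a bound. Of the probes called at least 2-fold 57.9% were higher here, 29.9% with normexp, 41.0% with median centring and 45.1% when probes had to be well above background on all 6 arrays. The probe with the largest rise measured in both groups, ASHG19AP1B100133106V5, went from -3.40 ± 0.09 to 0.65 ± 0.20, 16.6-fold (SD, n = 3; limma adjusted p = 6.02e-05). ASHG19LNC1A100028455V5 followed with a 13.2-fold rise (limma adjusted p = 0.000263). The largest falls were 8.66-fold in ASHG19AP1B143605168V5 and 7.65-fold in ASHG19AP1B103603458V5, with limma adjusted p of 0.0160 and 0.0123. Both were spread widely over the ALYREF arrays (SD 1.49 and 1.35, n = 3) and lost their call without ALYREF replicate 2, with a trended and robust variance model, with the slide row as a block and within the upper slide row; the larger of the 2 falls also lost it without ALYREF replicate 3. The files used here do not pair these identifiers with genes.

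The maker's identifiers fall into 3 large kinds, marked by the letters LNC, AP and V4, whose meaning is not stated in the files. Of the LNC probes 5008 of 20093 changed (24.9%), of the AP probes 4710 of 17801 (26.5%) and of the V4 probes 1457 of 7868 (18.5%), by limma. These shares are not compared at equal brightness. The median level was -1.76 in the LNC, -0.83 in the AP and -2.62 in the V4 probes. Between levels -5 and -4, 861 of 5605 probes of any kind were called, and between 6 and 7, 690 of 912. The median log2 fold change was 0.00 in the LNC probes and -0.03 in all others, and the LNC probes did not shift against the others (camera p = 0.330; 0.530 with an estimated correlation). Which direction prevailed depended on the scaling: 47.0% of the called probes were higher with ALYREF siRNA on the scale used here, 30.0% when arrays were centred on their median, and 68.5% when the 75th percentile was taken over probes well above background on all 6 arrays. Those scalings placed the median of all tested probes at -0.13 and 0.13, compared with -0.01 here. The 2 control probes for human GAPDH differed by -0.23 and -0.25 between groups on this scale, by -0.34 and -0.36 with median centring and by -0.09 and -0.10 with the last of these scalings.

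The change also followed the brightness of a probe. The 7003 probes with values on all 6 arrays at levels from 2 to 8, far above the 75th percentile, were lower with ALYREF siRNA in 79.9% of cases, with a median log2 fold change of -0.49. These 7003 probes held 62.7% of all probes called lower. The median was -0.69 between levels 5 and 6, 0.02 between -2 and -1, and 0.67 between -6 and -5. The drop was smaller in the brightest probes, at -0.24 between levels 8 and 9 and -0.07 between 9 and 10. The 366 probes between -6 and -5 lie near background. There a filter passed on 3 of 6 arrays can keep probes through the group that reads higher, so their 0.67 is not taken as an effect of the siRNA. The control arrays differed among themselves in bright probes too. Between levels 5 and 6 their median deviations were 0.34, 0.53 and 0.13, and those of the ALYREF arrays -0.18, -0.45 and -0.37. The median at levels 2 to 8 was -0.07 with quantile normalization and -0.16 with cyclic loess, compared with -0.50 on the scale used here, each over the 7233 tested probes of these levels, including those with a missing value.

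**Figure D2:**
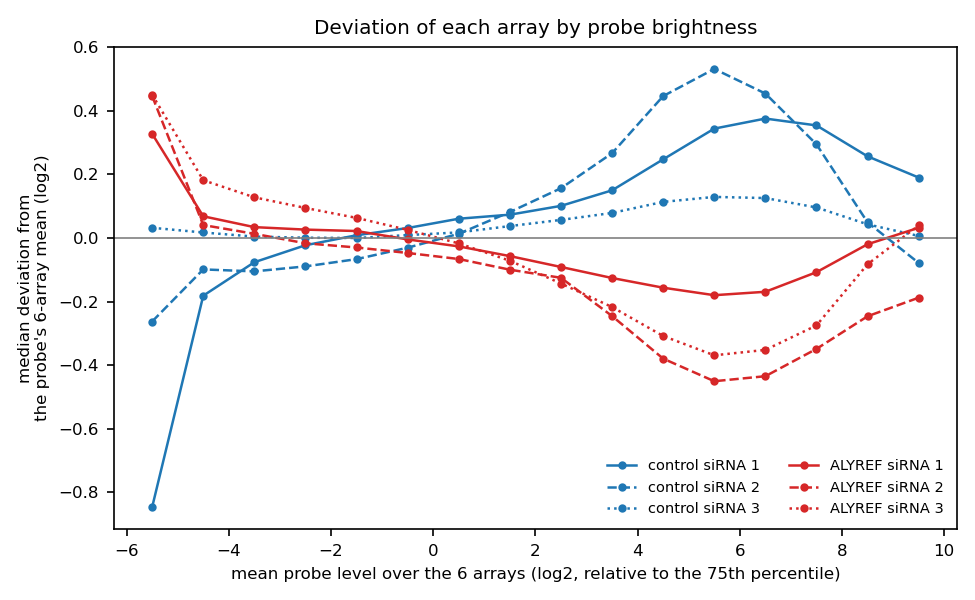
Median deviation of each array from the probes' means over all 6 arrays (y axis, log2) against the mean level of the probes (x axis, log2 relative to the 75th percentile), in bins 1 unit wide with at least 20 probes. Lines are single arrays, blue for control siRNA and red for ALYREF siRNA. Between levels 5 and 6 the control arrays lie at 0.13 to 0.53 and the ALYREF arrays at -0.45 to -0.18.

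With the slide row as a block 1075 probes were called, and within the upper row 869, in place of 11188, both with ALYREF replicate 1 as the only array of its arm; with the slide column as a block the count was 11092. The slide column fit rests on columns 1 and 2 alone with 1 residual degree of freedom, so its count does not settle whether slide position matters. Leaving out ALYREF replicate 3 gave 4964, control replicate 2 gave 5703 and control replicate 1 gave 6390.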

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

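Of the tests below, those on brightness alone were chosen after their results were seen. Groups of 3 arrays were too small to be searched for single arrays that stand apart.

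Of the control probes and the probes whose names start with CUST, all left out of the tests, 46 were well above background on all 6 arrays. The CUST probes are not marked as controls, and what they read is not stated. Among these, 2 read higher on all 3 ALYREF arrays than on all 3 control arrays. Chance sets 3 arrays fully apart from 3 others in 10% of probes, both directions together. The 2 alone do not exceed that share of the 46, but together with 15 probes that read lower on all 3 ALYREF arrays they do. The cause was not tested. DCP_20_3 differed by 0.31 log2 units (-4.05 ± 0.13 with control siRNA and -3.75 ± 0.17 with ALYREF siRNA, SD, n = 3). ERCC-00077_121 differed by 0.19 (-3.25 ± 0.08 and -3.07 ± 0.06, SD, n = 3). Both are dim. In the other direction, 15 of the 46 probes, CUST probes among them, read lower on all 3 ALYREF arrays. They include the bright ETG05_66023 and ERCC-00062_278, with differences of -0.58 and -0.27 log2 units, and the dimmer CUST_18_PI418767722, with -0.60.

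Bright probes were lower on the ALYREF arrays, with a median log2 fold change of -0.49 over 7003 probes at levels 2 to 8. At levels 2 to 5 brightness alone does not set the size of the drop. The medians of V4 probes lay 0.36, 0.29 and 0.32 log2 units below those of AP probes in the same unit bins. The AP medians were also below 0 and fell with level, at -0.14, -0.34 and -0.47, so a part that follows brightness is not excluded. At levels 5 to 8, which hold the largest drop, the 2 kinds differed by at most 0.0698, so brightness alone stays open there. A signal shared by many bright probes that varies between arrays whatever the siRNA is a candidate explanation: across these probes, the difference between control replicates 2 and 3 correlated with ALYREF siRNA minus control replicate 1 at r = -0.67, though no array enters both, and at -0.40 and -0.63 in the other pairings tried. At levels from -3 to 0 the first of these correlations was -0.11 over 17736 probes, and probes are not independent replicates. Brightness was not subtracted in these correlations. From levels 2 to 3 up to levels 5 to 6 the median deviation rose from 0.16 to 0.53 on control replicate 2 and from 0.10 to 0.34 on control replicate 1. A plain trend with brightness can therefore give them too. The pairing at -0.63 set ALYREF replicates 1 and 2 against each other, so it does not bear on arrays without that siRNA. How far ALYREF siRNA itself lowers these signals stays open, since the ALYREF arrays all lie on one side.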

How the results depend on the processing

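Cyclic loess and the slide blocks were chosen after seeing the data. Among probes called in both, no probe had the opposite sign in any of the 19 alternative fits, and no called result reversed. All these fits reuse the same arrays, and some the same fold changes, so such a reversal was hardly possible. The main counts were 11188 probes changed, 2290 at least 2-fold, 5008 LNC, 4710 AP and 1457 V4 probes and 12 named genes. Quantile normalization gave 7055, 1517, 3190, 2907 and 947 for the first 5, and the authors' values 6731, 1508, 3072, 2737 and 911. Normexp gave 1298 at least 2-fold. Without a filter on dim probes 7171 probes, 3300 LNC and 2835 AP probes and 6 named genes were called, over 60384 tested. The slide row block and the upper row alone set 1 ALYREF array, assumed to vary like the others, against 3 controls. The block gave 1075, 896, 570, 346, 159 and, by limma, 0 named genes (10 at an unadjusted p under 0.05). The upper row alone gave 869, 786, 474, 275, 119 and 1. The slide column block gave 4044 at least 2-fold, resting on columns 1 and 2 alone with 1 residual degree of freedom. Except where its construction is given, the cause was not tested.

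Leaving out 1 array gave 4964 to 11181 probes changed, 1526 to 3061 at least 2-fold, 2313 to 4910 LNC, 1955 to 4753 AP, 693 to 1505 V4 probes and 3 to 12 named genes. The lowest counts came without ALYREF replicate 3, except 1526 at least 2-fold without ALYREF replicate 2; without control replicate 1 or 2, 6390 and 5703 probes and 4 named genes each were called. Quantile normalization and cyclic loess kept 51.8% and 57.3% of the called probes. The share of higher calls was 47.0% on the scale used here, 40.7% with normexp, 60.4% with quantile normalization, 60.9% with the authors' values, 60.4% with cyclic loess, 30.0% with median centring and 68.5% with the 75th percentile over probes well above background. At least 2-fold it was 57.9%, and in the same order 29.9%, 76.1%, 76.8%, 77.4%, 41.0% and 78.1%, and 45.1% over probes well above background on all 6 arrays.

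With camera's preset correlation of 0.01, the mitosis and centromere genes passed in every fit with at least 2 arrays per group (medians 0.35 to 0.70). All share that preset and are not independent checks: with the estimate, 0.69, the call was lost (median 0.46, adjusted p = 0.658). The slide row fits (0.30) rest on 1 ALYREF array. The chromatin and transcription factor genes passed with quantile normalization (0.62, adjusted p = 0.0171), the authors' values (0.64, 0.0140) and cyclic loess (0.67, 0.0171), and their adjusted p ranged from 0.0140 to 0.685. The DNA replication and repair genes and the LNC probes did not pass in any. Of 19 alternatives, COL13A1 kept its call in 18, CCNA2 and SPDL1 in 17, ERGIC2 and DNTTIP2 in 13, WDHD1 in 11, KIF20A, SMARCAD1 and MOCOS in 10, ITGB3BP and CENPE in 8 and NOC3L in 5.

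The replicate block gave 9449 probes changed, 2153 at least 2-fold and 8 named genes. Deviations of arrays with the same number correlated at -0.05, -0.15 and 0.10, so the numbers are not taken to pair the samples.

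A block for slide or scan was not run because all arrays share 1 of each, and alternatives for ALYREF, for genes by class, for the lists and for single-exon genes were not run because too few probes have names. Signal over background limits the dim probes, since 67.3% of the spots were well above background on control replicate 1 and at least 74.4% on the other arrays.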

Other observations

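The tests on brightness and on the whole panel in the mitosis paragraph were chosen after their results were seen, as was the search for neighbouring catalogue numbers.

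Of the 4 tested genes of the blood and immune and the liver groups, 0 passed in limma and 1, SERPIND1, had an unadjusted p under 0.05. ZAP70 and CD69 of immune cells and SAA4 of the liver were not well above background on any of the 6 arrays. The clotting regulator SERPIND1 had a log2 fold change of -0.35 (SE 0.13, limma adjusted p = 0.0924), and the urea cycle enzyme CPS1 one of 0.11 (SE 0.14, limma adjusted p = 0.626). The blood cell gene RHOH stood at 8.97 ± 0.10 with control siRNA and 8.82 ± 0.09 with ALYREF siRNA (SD, n = 3; limma adjusted p = 0.378). RHOH was the brightest named gene tested, between levels 8 and 9, where the median log2 fold change of all probes was -0.24. Whether so bright a signal comes from RHOH transcripts was not tested. LMO2, the other blood cell gene tested, had a log2 fold change of 0.03 (SE 0.15, limma adjusted p = 0.898). These genes were named after their values were seen.

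The rise of the mitosis and centromere genes was set against 3 technical explanations, of which the shift with brightness runs the other way, since the medians of all probes in the brightness bins of these genes lay between -0.259 and -0.0930. ALYREF replicate 2 read highest, but without it the median was 0.35 (camera adjusted p = 0.00716). A shift of the whole panel would move all its genes alike. The median of the 7 genes exceeded that of the other 38 by 0.41 (permutation of genes, 100000 resamples, two-sided p = 0.0281). That permutation treats the genes as independent, while the correlation that camera estimated within the 7 was 0.69, so its p can be too small. A larger share of cells in G2 and M phase, or a change in the transcripts themselves, may lie behind it; neither was tested. The loss of the call with an estimated correlation and the missing check of the knockdown leave it a hypothesis, and slide row stays open.

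LNC probes with neighbouring catalogue numbers tended to rise together. Among 6004 pairs of probes whose numbers lie at most 5 apart, both had risen at least 2-fold in 77 pairs, compared with 8 among as many random pairs. Neighbours by number were hardly closer on the slide, at a median distance of 134 grid positions, compared with 137 in random pairs. The correlation of log2 fold changes was weak, at r = 0.0990 over neighbours and 0.00172 over random pairs; probes are not independent replicates. It was 0.0570 in pairs far apart on the slide, 0.137 in nearer pairs, 0.0944 after the median of each brightness bin was subtracted and, after the same subtraction, 0.0465 over the 2652 pairs whose levels lie at least 3 log2 units apart. With the correlation over all pairs this low, closeness on the slide and shared brightness cannot be told apart from other sources, such as neighbouring probes that may read the same transcript.

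One control probe split the arrays across the groups. ERCC-00097_63 stood at 0.38 on control replicate 1 and 0.31 on ALYREF replicate 2, and at 3.27 to 4.46 on the other 4 arrays. The first 2 arrays share column 1 of the slide, and they also lay apart from the other 4 on the second principal component, which held 12.1% of the variance.

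The 6 arrays can be split into 3 and 3 in 10 ways, so no share under 0.05 can be reached. In 1 of the 10, the real one, limma called any probe: 11188 probes, 2290 at least 2-fold, 5008 LNC, 4710 AP and 1457 V4 probes and 12 named genes, with 0 the highest of the others in each case. At an unadjusted p under 0.05 the real split gave 17313 probes and the highest other 1893, with 19 and 2 named genes. Each of the 9 other splits mixes arrays of both groups. Any difference between the groups, whatever its cause, then widens the spread within each side and lowers these counts. The low counts of the other splits therefore do not tell the siRNA from slide row. For the mitosis and centromere genes 1 of 10 splits gave as small an adjusted p (0.00400; the smallest other 0.00736), a call lost with an estimated correlation (adjusted p = 0.658). Of the 9 other splits, 4 also passed 0.05 for these genes, with medians of 0.20 to 0.31 toward the side with 2 ALYREF arrays, while 4 passed for DNA replication and repair and 5 for chromatin and transcription factors, where the real split did not. The count was 4 for the LNC probes (0.330; smallest other 0.0783), 10 for DNA replication and repair (0.742; smallest other 1.20e-05) and 6 for chromatin and transcription factors (0.138; smallest other 0.00736). The smallest for DNA replication and repair came from control replicate 1 with ALYREF replicates 1 and 3 against the rest, which points to a structure of the panel values that crosses the groups.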
